A study of Mus musculus with 12 samples.

How the data were processed

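Total RNA of 4 sorted mouse thymocyte subsets, extracted with Trizol directly after isolation and without culture, had been hybridised to 12 Affymetrix arrays, 3 per subset, per the labels' protocols. The design text names more than 1 version of the mouse expression chip, and the value table holds 45101 probe sets. The groups DN, DP, CD4SP and CD8SP and the replicate numbers 1 to 3 were taken from the sample titles.

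The authors deposited 1 value per probe set and array on a log scale, read here as log2, with values between -9.94 and 10.28 and 0 missing. The log base is not given in the sources used here. MAS5 is named in the submitters' processing notes without a version or a role. In the deposited table each probe set has had the mean of the 3 DP arrays subtracted, as the values show: the largest absolute DP mean over all probe sets is 1.27e-06. Expression levels and signal over background were therefore lost, no filter on dim probe sets could be applied, and DP lies at 0 for each gene. The values of DN replicate 1 are rounded to 3 decimals. No further normalization was applied, since the array medians lay close together (between -0.10 and 0.05). No genome build was named, so no coordinates are given.

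Probe sets were named from the platform annotation of the array. Of all probe sets 34958 had 1 gene symbol, 932 had several and 9211 were not named there. The 64 control probe sets were left out, which left 34945 probe sets with 1 symbol. Gene symbols were checked by gene ID against a RefSeq gene table of GRCm38.p6, which held 34741 of these probe sets, and 0 symbols were updated. A gene's value is the mean of its probe sets, for 18193 genes, of which 9183 had 1 probe set and 9010 more than 1. Probe sets of 1 gene can disagree: in DP against DN, CD4SP against DP, CD8SP against DP and CD4SP against CD8SP, 247, 89, 245 and 19 genes had probe sets called in opposite directions.

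All 12 arrays were fitted together as 4 group means with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that the groups share one estimate of the spread. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within each comparison over all genes, and genes were called at an adjusted p under 0.05. The comparisons were DP minus DN, CD4SP minus DP, CD8SP minus DP and CD4SP minus CD8SP. The last one also tests whether the changes from DP differ between the single-positive subsets. The preset design had used the probe set with the highest mean and a variance trend on the mean value. Since the mean of these values is not a signal level, the mean over probe sets and eBayes without the trend, which had been listed as alternatives beforehand, were made the main choices after the values were seen, and both preset choices were run as alternatives.

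Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, for 25 lists in 4 comparisons, with Benjamini-Hochberg adjustment over the 100 tests. The 16 theme lists were DN stage and progenitor genes, DP stage genes, maturation and egress genes, CD4 lineage genes, CD8 lineage genes, genes induced by T cell receptor signalling and selection, cell cycle genes, the BCL2 family, chemokine and egress receptors, T lineage transcription factors, the T cell receptor complex with its proximal signalling genes, glycolysis genes, cholesterol biosynthesis genes, the MHC class I pathway, interferon-stimulated genes and the Gimap family. The 9 marker lists held markers of B cells, NK and innate lymphoid cells, myeloid and dendritic cells, γδ T cells, erythroid cells, thymic stroma and regulatory T cells, sex-linked genes, and dissociation and heat shock genes. List members with no value in the table used are not analysed here. The lists and the design were fixed before the data were examined. The named genes are the sort genes Cd4, Cd8a and Cd8b1, the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap between the groups, and up to 4 members of each theme list with the lowest adjusted p, plus called members that went against their list. Symbols that are only clone or predicted-gene identifiers were passed over. Marker genes and the genes singled out in the closing observations were named after their values were seen.

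The comparisons with DP share 3 arrays, so 100 simulations of unchanged groups were set against those arrays, and the overlap of independent lists was taken as the product of the list sizes over the genes tested. The fit was tested on simulated data with 200 changed genes among 18193. It recovered 26.9%, 83.6% and 93.9% of genes changed by 0.5, 1 and 2 (log2) in DP against DN, 22.4%, 74.6% and 93.9% in CD4SP against DP, 29.9%, 71.6% and 93.9% in CD8SP against DP, and 28.4%, 62.7% and 93.9% in CD4SP against CD8SP. It called 7, 10, 4 and 9 unchanged genes. The real comparisons called 12.7% to 39.0% of genes, a far larger share than was changed here. The Benjamini-Hochberg adjustment is stricter with few changed genes, so the recovered shares need not hold for the real data. A list of cell cycle genes shifted by 1 was called in each comparison, and 0 of the 24 other lists were. The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.68. This run therefore cannot show how often lists of correlated genes are called falsely.

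The alternatives were arrays centred on their medians, all probe sets tested, the replicate number as a block, only the 6 arrays compared, array weights, and each array left out in turn. The variance trend and the probe set with the highest mean, both preset, became alternatives after the values were seen. Chosen after seeing the data were the probe set with the smallest spread, only probe sets whose spread within groups lay under the median of all probe sets, the arrays numbered 1 as a factor, and DN replicate 1 and CD8SP replicate 1 left out together. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.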

Results

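Expression was measured in 4 subsets of mouse thymocytes, sorted from C57BL/6 mice and read on 3 Affymetrix arrays each. DN cells lacked CD4, CD8α and TCRβ, DP cells carried both CD4 and CD8α, and the CD4SP and CD8SP cells carried 1 coreceptor with high TCRβ. These stages follow one another in the thymus, from DN through DP to either single-positive subset. The deposited values are log values relative to the mean of the 3 DP arrays, taken here as log2, so that DP lies at 0 for each gene and absolute levels are lost. Values are given as log2 differences ± the standard error of the limma fit, over 3 arrays per group, or as a group mean ± SD where stated. A gene was called at an adjusted p under 0.05, and "rose" and "fell" are used only of called genes. The labels do not say whether the replicates came from separate mice, so the p-values measure only the spread between these arrays. The number of arrays limits the precision.

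The 4 subsets separated from each other on the first 3 principal components of the 18193 genes, which held 47.1%, 25.4% and 8.19% of the variance. CD8SP replicate 1 and DN replicate 1 stood apart from the rest of their groups. The former had higher hybridisation controls (0.84, against -0.16 to 0.08 on the other arrays), the largest 3′ minus 5′ difference of the Gapdh control (0.37) and the lowest array weight (0.28). The latter had the next lowest weight (0.53). On that array Cd4 lay at -3.88, against -6.49 and -5.29 on the other DN arrays, and the B cell gene Ms4a1 lay at 3.33, against 5.93 and 5.63. The heat shock gene Hspa1b was highest on the array numbered 1 in each group (3.76 in DN, 1.12 in DP, 1.75 in CD4SP and 1.51 in CD8SP). Residuals of the arrays numbered 1 correlated by 0.11 to 0.16, against -0.16 to 0.08 between arrays of different numbers. Xist lay at 2.03 on DN replicate 3 and between -1.05 and 0.64 on the other arrays.

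**Figure D1:**
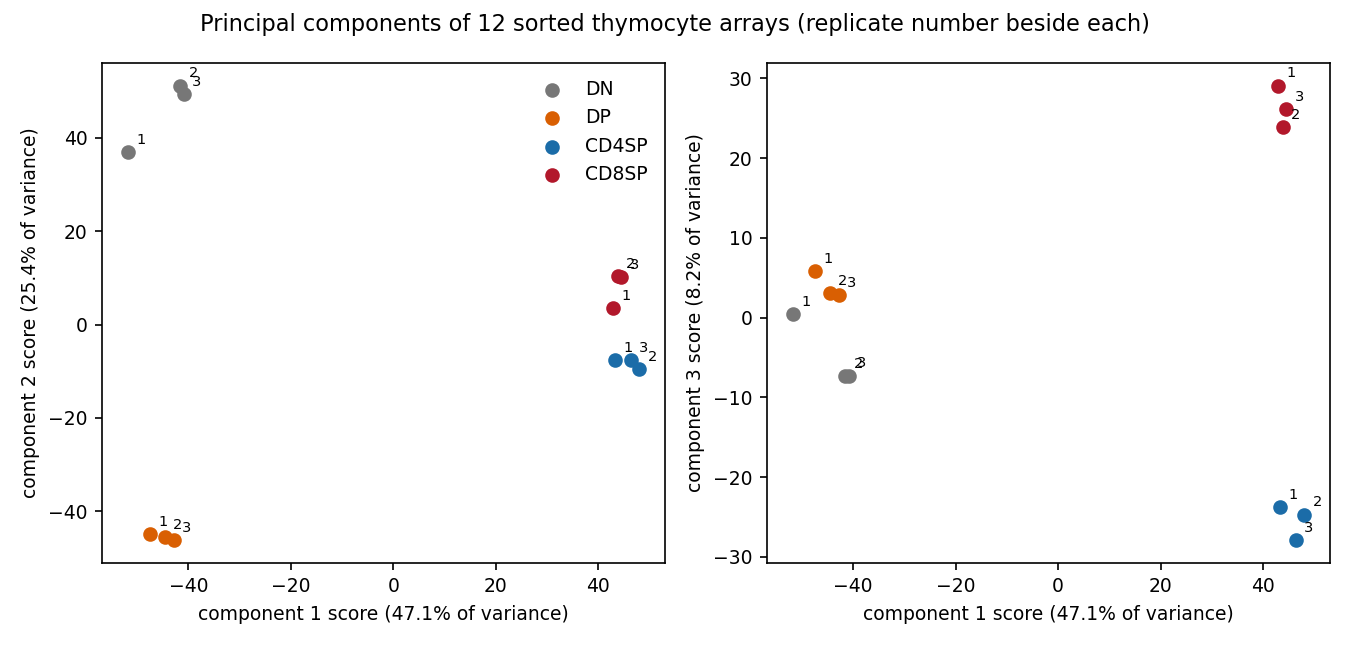
Scores of the 12 arrays on principal components 1 and 2 (left) and 1 and 3 (right), with the share of variance on each axis. Each point is 1 array, coloured by subset and numbered by replicate. Component 1 parts the single-positive arrays from DN and DP, component 2 parts DN from DP, and component 3 parts CD4SP from CD8SP.

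The first comparison set DP cells against the DN cells that precede them. Among the sort genes, Cd4 rose by 5.22 ± 0.50 in DP, Cd8a by 3.72 ± 0.38 and Cd8b1 by 3.47 ± 0.29. The largest rise was that of Slc7a11, which encodes the cystine-glutamate antiporter subunit xCT, at 6.91 ± 0.18 (adjusted p = 3.41e-09). After Cd4 followed Medag (4.83 ± 0.40), the nicotinic receptor gene Chrna9 (4.76 ± 0.27), Ccdc153 (4.56 ± 0.89), the amino acid transporter gene Slc6a19 (4.33 ± 0.50), Tdrp (3.83 ± 0.24) and the transcription factor gene Pou6f1 (3.77 ± 0.31). The largest fall was that of Camp, which encodes the neutrophil granule peptide cathelicidin, at -8.60 ± 0.57 (adjusted p = 1.22e-06), a 389-fold difference. Gpr25, an orphan receptor gene, fell by 8.34 ± 0.18. The granule and calprotectin genes Lcn2 (-7.26 ± 0.56), S100a9 (-7.61 ± 0.67) and S100a8 (-6.72 ± 0.65) fell, the γ chain segment Trgv4 fell by 6.56 ± 0.23, and the immunoglobulin gene Igha fell by 6.47 ± 0.26.

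In all, 3240 genes were higher and 3420 lower in DP than in DN, of which 521 and 1011 differed at least 2-fold. The 3 arrays of one group did not overlap the 3 of the other for 49.8% of genes, where chance gives 10% for 3 against 3. The genes of the DN stage list, which are active in early progenitors, changed together. Of its 15 measured members 0 rose, 14 fell and 1 was not called, and 15 fell when adjusted over the list alone. Il2ra, the CD25 chain by which DN stages are sorted, fell by 4.56 ± 0.29, the receptor genes Kit (-2.24 ± 0.19) and Notch1 (-1.45 ± 0.12) fell, and the homeobox gene Hhex fell by 1.94 ± 0.19 (camera, adjusted p = 1.92e-08, and adjusted p = 0.288 with an estimated correlation). Of 13 measured DP stage genes 12 rose, 0 fell and 1 was not called, and 13 rose when adjusted over the list alone. Plxnd1 rose by 3.70 ± 0.23, Satb1 by 1.96 ± 0.13 and Themis, a regulator of thymocyte selection, by 1.88 ± 0.09 (camera, adjusted p = 7.78e-10, and adjusted p = 0.146 with an estimated correlation).

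Genes of the T cell receptor complex and of its proximal signalling were higher in DP, where the marker lists of NK, myeloid and B cells were lower. Of 20 measured members 17 rose, 0 fell and 3 were not called, while 17 rose and 1 fell when adjusted over the list alone. Cd6 rose by 2.04 ± 0.16, Ptprc by 1.28 ± 0.11 and Lat, an adaptor of the receptor, by 0.94 ± 0.10 (camera, adjusted p = 1.38e-07, and adjusted p = 0.268 with an estimated correlation). Among 28 T lineage transcription factors 10 rose, 4 fell and 14 were not called, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.26, median -0.010, mean 0.10). Nfatc3 rose by 1.57 ± 0.10, Ets2 by 2.04 ± 0.17 and Tcf12 by 0.98 ± 0.08, whereas Klf2 fell by 1.65 ± 0.31. Without DN replicate 1, 8 of these factors fell instead of 4, and 7 fell with the arrays numbered 1 as a factor.

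Glycolysis and cholesterol biosynthesis genes were lower in DP. Of 13 measured glycolysis genes 1 rose, 9 fell and 3 were not called, with the same counts adjusted over the list alone. Tpi1 fell by 1.98 ± 0.11, Pgam1 fell by 1.90 ± 0.11 and Aldoa fell by 1.37 ± 0.08 (camera, adjusted p = 1.26e-04, and adjusted p = 0.33 with an estimated correlation). Of 13 cholesterol biosynthesis genes 0 rose, 10 fell and 3 were not called, again with the same counts adjusted over the list alone. Idi1 fell by 1.73 ± 0.18, Sqle fell by 1.37 ± 0.13 and Hmgcs1 fell by 1.13 ± 0.10 (camera, adjusted p = 3.24e-05, and adjusted p = 0.233 with an estimated correlation). Of 29 cell cycle genes 1 rose, 14 fell and 14 were not called, and 2 rose and 14 fell when adjusted over the list alone. With the arrays numbered 1 as a factor, 6 rose instead of 1. Those that fell included the replication licensing genes Mcm6 (-1.13 ± 0.09), Mcm3 (-1.07 ± 0.08), Mcm4 (-0.90 ± 0.08) and Mcm2 (-0.87 ± 0.08). Top2a rose by 1.02 ± 0.33, a call lost in 7 alternatives, DN replicates 2 and 3 and each DP array left out among them. The call for this list (adjusted p = 0.00538) ended with an estimated correlation (adjusted p = 0.641), without DN replicate 1 (adjusted p = 0.0619) and without that array and CD8SP replicate 1 together (adjusted p = 0.0979), with a lowest adjusted p of 4.46e-04 over the alternatives.

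MHC class I pathway and interferon-stimulated genes were also lower in DP. Of 14 measured MHC class I pathway genes 1 rose, 11 fell and 2 were not called, and 2 rose and 11 fell when adjusted over the list alone. H2-K1 fell by 2.03 ± 0.20 and Psmb10, a subunit of the immunoproteasome, fell by 1.39 ± 0.13 (camera, adjusted p = 4.05e-05, and adjusted p = 0.33 with an estimated correlation). Of 18 interferon-stimulated genes 3 rose, 10 fell and 5 were not called, and 4 rose and 12 fell when adjusted over the list alone. Ifit3 fell by 2.80 ± 0.45 and Bst2 fell by 1.79 ± 0.15, while Igtp rose by 1.38 ± 0.14 (camera, adjusted p = 0.0266, and adjusted p = 0.674 with an estimated correlation). That list's call was also lost without DN replicate 2 (adjusted p = 0.0501) and without DP replicate 1 (adjusted p = 0.0604), with a lowest adjusted p of 5.11e-04 over the alternatives. Of 15 maturation and egress genes 3 rose, 9 fell and 3 were not called, with the same counts adjusted over the list alone. Il7r, the receptor chain for interleukin 7, fell by 4.92 ± 0.36 and Bcl2 fell by 1.78 ± 0.14, while Cd52 rose by 1.34 ± 0.33 (camera, adjusted p = 0.0323, and adjusted p = 0.674 with an estimated correlation). This call was lost without DN replicate 2, DP replicate 1 or CD8SP replicate 1 and with the probe set of the smallest spread (adjusted p from 2.84e-04 to 0.0713 over the alternatives). Of 13 BCL2 family members 5 rose, 3 fell and 5 were not called, with the same counts adjusted over the list alone (adjusted p = 0.361). The number that rose was 3 with the probe set of the highest mean and also with that of the smallest spread. Bcl2l1, which encodes the survival protein BCL-XL, rose by 2.25 ± 0.15 and Mcl1 by 0.99 ± 0.09.

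The marker lists of NK and innate lymphoid cells, myeloid cells, B cells and γδ T cells were higher on the DN arrays, whose gate is described in the labels by the absence of CD4, CD8α and TCRβ alone (camera, adjusted p = 1.23e-04, 0.00126, 0.0364 and 6.1e-04 in that order). Those of erythroid cells and thymic stroma were not called. Of 9 NK cell and innate lymphoid markers 8 fell from DN to DP, with Tyrobp at -3.49 ± 0.35 (adjusted p = 0.33 for the list with an estimated correlation). Of 15 myeloid and dendritic cell markers 7 fell, among them Lyz2 (-4.17 ± 0.47) and H2-Ab1 (-4.15 ± 0.44), and 9 fell when adjusted over the list alone (adjusted p = 0.478 for the list with an estimated correlation). Of 9 B cell markers 3 fell, led by Ms4a1 (-4.96 ± 0.52), and 7 fell without DN replicate 1 (adjusted p = 0.548 for the list with an estimated correlation). The B cell list lost its call without DN replicate 2 or 3, DP replicate 1 or CD8SP replicate 1 and with the probe set of the smallest spread (adjusted p from 2.62e-04 to 0.0837 over the alternatives). The 5 measured γδ T cell markers all fell, among them Cd163l1 (-2.78 ± 0.23) (adjusted p = 0.306 for the list with an estimated correlation), and with the probe set of the smallest spread 3 fell and the list call was lost (adjusted p = 0.0905, and from 7.86e-05 over the alternatives). Adjusted over the list alone, 8 NK cell, 3 B cell and 5 γδ T cell markers fell. Of 12 thymic stroma markers 0 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.763, median 0.14, mean -0.12), and 3 rose without DN replicate 3. Of 5 erythroid markers 0 fell and 1 rose, Hba-a1 (0.25 ± 0.09), a call lost in 11 alternatives and when adjusted over the list alone (adjusted p = 0.596 for the list, median 0.25). The NK cell, myeloid, B cell and γδ T cell markers move with the lower MHC class I, interferon, maturation and CD8 lineage genes and the higher T cell receptor complex genes of DP. These markers also move with the lower glycolysis, cholesterol biosynthesis and cell cycle genes of DP. Of 16 CD8 lineage genes, several of which NK cells also express, 2 rose, 11 fell and 3 were not called, with the same counts adjusted over the list alone. Nkg7 fell by 4.88 ± 0.39 and Cst7 fell by 3.35 ± 0.35 (camera, adjusted p = 0.0114, and adjusted p = 0.515 with an estimated correlation).

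**Figure D2:**
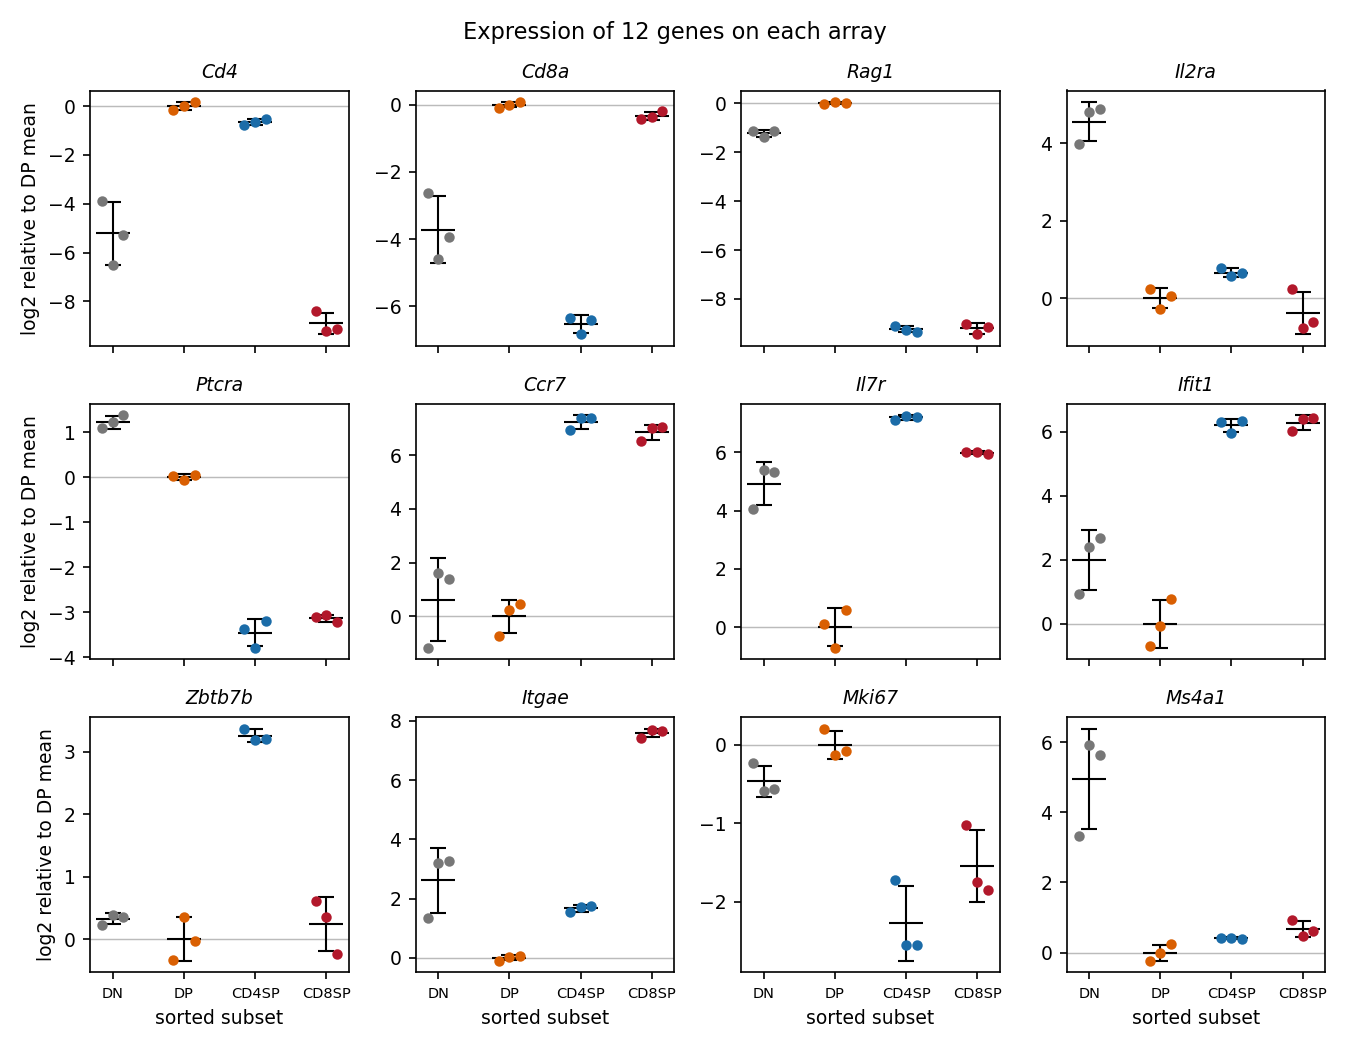
Log2 expression relative to the DP mean of 12 genes on each array, by subset. Points are single arrays in the order of their replicate numbers, and bars give the mean ± SD of 3 arrays. Ms4a1 lies at 3.33, 5.93 and 5.63 on the DN arrays, and Cd4 at -3.88, -6.49 and -5.29.

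The second comparison followed DP cells into the CD4SP subset. Cd8a fell by 6.53 ± 0.38 and Cd8b1 fell by 5.43 ± 0.29, while Cd4 differed by -0.64 ± 0.50 and was not called (adjusted p = 0.374). In the fit of only the 6 arrays compared, this Cd4 difference was called (adjusted p = 0.00534, and up to 0.537 over the alternatives). The recombinase genes Rag1 (-9.24 ± 0.12, adjusted p = 1.17e-11, 604-fold) and Rag2 (-8.95 ± 0.23) had the largest falls, followed by Endou (-8.93 ± 0.12), Morc1 (-8.86 ± 0.32) and Dhrs3 (-7.90 ± 0.17). The largest rise was that of the GTPase gene Gimap4, at 7.41 ± 0.54 (adjusted p = 2.04e-06). The chemokine receptor genes Ccr7 and Ccr8 rose by 7.23 ± 0.61 and 6.13 ± 0.35, and Il7r by 7.20 ± 0.36. The protease gene Ctss rose by 7.13 ± 0.48, Smad7, an inhibitor of TGFβ signalling, by 7.01 ± 0.36, and the cyclin gene Ccnd2 by 6.62 ± 0.31.

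In all, 2992 genes were higher and 2950 lower in CD4SP than in DP, of which 860 and 736 differed at least 2-fold, and for 49.4% of genes the 2 groups did not overlap (chance gives 10%). With the probe set of the highest mean, which is the one most above DP, 3388 were higher and 2054 lower. Of 13 DP stage genes 0 rose, 12 fell and 1 was not called, with the same counts adjusted over the list alone. Arpp21 fell by 7.25 ± 0.20 and Dntt, the terminal transferase that adds junctional nucleotides, fell by 4.98 ± 0.16 (camera, adjusted p = 1.93e-13, and adjusted p = 0.0919 with an estimated correlation). Of 15 maturation and egress genes 14 rose and 1 fell, with the same counts adjusted over the list alone. Bcl2 rose by 3.74 ± 0.14, the integrin gene Itgb7 by 3.64 ± 0.18 and H2-K1 by 3.92 ± 0.20, while the interferon γ receptor gene Ifngr1 fell by 2.57 ± 0.12 (camera, adjusted p = 5.39e-11, and adjusted p = 0.268 with an estimated correlation). Of 12 CD4 lineage genes 10 rose, 0 fell and 2 were not called, with the same counts adjusted over the list alone. Izumo1r rose by 5.61 ± 0.12, Tnfrsf4, which encodes OX40, by 3.71 ± 0.12, and Zbtb7b, which encodes the CD4 lineage factor ThPOK, by 3.26 ± 0.21 (camera, adjusted p = 3.53e-07, and adjusted p = 0.0842 with an estimated correlation). The CD8 lineage list was called higher in CD4SP as well. Of its 16 members 9 rose, 2 fell and 5 were not called, with the same counts adjusted over the list alone. Dapl1 rose by 3.89 ± 0.22 and Crtam by 3.20 ± 0.21, and those that fell were the sort genes Cd8a and Cd8b1 (camera, adjusted p = 0.0146, and adjusted p = 0.521 with an estimated correlation). Of 7 regulatory T cell markers, of which Ctla4, Tnfrsf4 and Foxp3 are also in the CD4 lineage list, 5 rose and 0 fell, with the same counts adjusted over the list alone. Gpr83 rose by 4.40 ± 0.17 and Tnfrsf18 by 2.15 ± 0.22 (camera, adjusted p = 8.54e-05, and adjusted p = 0.0842 with an estimated correlation). Of 5 γδ T cell markers 3 rose, with the same count adjusted over the list alone (camera, adjusted p = 0.0436, and adjusted p = 0.521 with an estimated correlation), a call lost in 7 of 17 other alternatives (adjusted p from 0.0231 to 0.532). These were the omissions of DP replicate 2, CD4SP replicate 2 and CD8SP replicates 1 and 3, the replicate block, the arrays numbered 1 as a factor and the probe set of the smallest spread. The B cell, NK cell, myeloid, erythroid and thymic stroma lists were not called (adjusted p from 0.454 to 0.675).

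Genes induced by T cell receptor signalling were higher in CD4SP. Of 18 measured members 15 rose, 0 fell and 3 were not called, and 16 rose when adjusted over the list alone. Itm2a rose by 3.74 ± 0.10, Nab2 by 3.01 ± 0.18 and Myc by 2.19 ± 0.16 (camera, adjusted p = 2.3e-10, and adjusted p = 0.233 with an estimated correlation). Of 14 dissociation and heat shock genes, of which Egr1 and Junb are also in that list, 6 rose, 1 fell and 7 were not called, and 6 rose and 2 fell when adjusted over the list alone. Ier2 rose by 2.21 ± 0.16 and Dusp1 by 1.01 ± 0.11, while Jun fell by 1.44 ± 0.32 and Hspa1a (0.10 ± 0.72) and Hspa1b (0.50 ± 0.80) were not called (camera, adjusted p = 0.0484, and adjusted p = 0.386 with an estimated correlation). This call was lost without DN replicate 2, DP replicate 2, CD4SP replicate 1 or any CD8SP array, with the arrays numbered 1 as a factor and with the probe set of the smallest spread (adjusted p from 0.023 to 0.132 over the alternatives). Of 29 cell cycle genes 0 rose, 25 fell and 4 were not called, and 27 fell when adjusted over the list alone. Ccnb2 fell by 2.51 ± 0.21, Rrm2 fell by 2.42 ± 0.15 and Aurkb fell by 2.21 ± 0.18 (camera, adjusted p = 3.58e-16, and adjusted p = 0.233 with an estimated correlation). Of 18 interferon-stimulated genes 16 rose, 1 fell and 1 was not called, with the same counts adjusted over the list alone. Ifit1 rose by 6.20 ± 0.44, Usp18 by 3.24 ± 0.21 and Irgm1 by 2.80 ± 0.16, while Ly6e fell by 1.26 ± 0.14 (camera, adjusted p = 3.45e-10, and adjusted p = 0.3 with an estimated correlation). Of 14 MHC class I pathway genes 11 rose, 1 fell and 2 were not called, and 12 rose when adjusted over the list alone. Nlrc5, the transactivator of MHC class I genes, rose by 5.15 ± 0.26 and B2m by 1.59 ± 0.12, while Tap2 fell by 0.61 ± 0.13 (camera, adjusted p = 7.8e-08, and adjusted p = 0.233 with an estimated correlation). Of 8 Gimap family members 6 rose, 0 fell and 2 were not called, with the same counts adjusted over the list alone. Gimap3 rose by 6.11 ± 0.44 and Gimap7 by 2.50 ± 0.16 (camera, adjusted p = 2.3e-04, and adjusted p = 0.391 with an estimated correlation). Of 13 glycolysis genes 6 rose, 1 fell and 6 were not called, with the same counts adjusted over the list alone. Slc2a3 rose by 1.37 ± 0.18 and Aldoa by 1.17 ± 0.08, while Tpi1 fell by 0.58 ± 0.11 (camera, adjusted p = 0.0143, and adjusted p = 0.521 with an estimated correlation). Of 13 cholesterol biosynthesis genes 1 rose, 4 fell and 8 were not called, and 5 fell when adjusted over the list alone. Sqle fell by 1.67 ± 0.13 and Insig1 fell by 1.64 ± 0.17, while Mvd rose by 0.49 ± 0.09 (camera, adjusted p = 0.0155, and adjusted p = 0.396 with an estimated correlation). Of 20 T cell receptor complex and signalling genes 9 rose, 3 fell and 8 were not called, with the same counts adjusted over the list alone. Cd2 rose by 3.30 ± 0.15 and Fyn by 1.88 ± 0.14, while Themis fell by 2.25 ± 0.09 (camera, adjusted p = 0.0266, and adjusted p = 0.552 with an estimated correlation), and without DP replicate 3, CD4SP replicate 2 or CD4SP replicate 3 the number that fell was 1.

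Transcription factor genes moved in both directions. Of 28 measured members 11 rose, 9 fell and 8 were not called, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.43). Klf2, which drives thymic egress genes, rose by 5.46 ± 0.31, Foxo1 by 1.88 ± 0.13 and Lef1 by 1.59 ± 0.07, whereas Myb fell by 4.07 ± 0.10 and Nfatc3 fell by 1.83 ± 0.10. Of 11 chemokine and egress receptors 7 rose, 2 fell and 2 were not called, and 8 rose when adjusted over the list alone. S1pr1, the sphingosine phosphate receptor needed for exit from the thymus, rose by 4.88 ± 0.36, whereas Cxcr4 (-3.25 ± 0.50) and Ccr9 (-1.54 ± 0.12) fell (camera, adjusted p = 0.0163, and adjusted p = 0.521 with an estimated correlation). Of 13 BCL2 family members 3 rose, 5 fell and 5 were not called, and 6 fell when adjusted over the list alone (adjusted p = 0.223). Bcl2l1 fell by 1.79 ± 0.15 and the proapoptotic gene Bid fell by 1.93 ± 0.17. With 1 probe set per gene, either that with the highest mean or that with the smallest spread, 3 members of this family fell instead of 5. Of 15 DN stage genes 3 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.858, median 0.20, mean -0.09). The number that rose was 5 with array weights, with only the 6 arrays compared and without DN replicate 1 and CD8SP replicate 1 together. With the probe set of the highest mean, the number that fell was 1. Ptcra, the pre-TCR α chain, fell by 3.46 ± 0.14 and Dtx1 rose by 2.17 ± 0.18.

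The third comparison followed DP cells into the CD8SP subset. Cd4 fell by 8.90 ± 0.50 (479-fold), while Cd8a differed by -0.33 ± 0.38 (adjusted p = 0.526) and Cd8b1 by -0.61 ± 0.29 (adjusted p = 0.125), neither called. Both were called when only the 6 arrays compared were fitted (adjusted p = 0.0467 for Cd8a and 0.00881 for Cd8b1), and Cd8b1 also without DN replicate 1 (adjusted p = 0.0054). Over the alternatives the adjusted p of Cd8a reached 0.66 and that of Cd8b1 0.271. The largest rise was that of Itgae, which encodes the CD103 integrin chain, at 7.60 ± 0.40 (adjusted p = 1.66e-07). Nkg7, a gene of cytotoxic granules, rose by 7.52 ± 0.39, Smad7 by 7.17 ± 0.36, Ctss by 7.08 ± 0.48 and Ccr7 by 6.85 ± 0.61. Rag2 (-9.46 ± 0.23, adjusted p = 8.74e-10), Rag1 (-9.21 ± 0.12, adjusted p = 1.1e-11), Morc1 (-9.13 ± 0.32), Endou (-8.98 ± 0.12) and Dhrs3 (-7.92 ± 0.17) had the largest falls besides Cd4.

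In all, 3307 genes were higher and 3796 lower in CD8SP than in DP, of which 904 and 836 differed at least 2-fold, and for 48.6% of genes the 2 groups did not overlap (chance gives 10%). With the probe set of the highest mean in place of the mean over probe sets, 4003 genes were higher and 2483 lower. Of 16 CD8 lineage genes 13 rose, 0 fell and 3 were not called, with the same counts adjusted over the list alone. Dapl1 rose by 6.10 ± 0.22 and Crtam, a surface receptor of cytotoxic T cells, by 5.81 ± 0.21 (camera, adjusted p = 2.59e-09, and adjusted p = 0.186 with an estimated correlation). Of 12 CD4 lineage genes 5 rose, 2 fell and 5 were not called, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.245). Izumo1r rose by 4.64 ± 0.12 and Icos by 2.49 ± 0.28, whereas Gata3 fell by 1.33 ± 0.22. Of 7 regulatory T cell markers 5 rose and 0 fell, with the same counts adjusted over the list alone, among them Gpr83 (3.40 ± 0.17) (camera, adjusted p = 0.0173, and adjusted p = 0.233 with an estimated correlation). Of 13 DP stage genes 0 rose, 11 fell and 2 were not called, with the same counts adjusted over the list alone. Arpp21 fell by 6.88 ± 0.20 and Aqp11 fell by 4.26 ± 0.13 (camera, adjusted p = 8.74e-12, and adjusted p = 0.0976 with an estimated correlation). Of 15 maturation and egress genes 14 rose and 1 fell, with the same counts adjusted over the list alone. Itgb7 rose by 4.12 ± 0.18, H2-D1 by 3.08 ± 0.17 and Bcl2 by 3.71 ± 0.14, while Ifngr1 fell by 2.43 ± 0.12 (camera, adjusted p = 2.63e-10, and adjusted p = 0.288 with an estimated correlation).

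Interferon-stimulated and MHC class I pathway genes were higher in CD8SP than in DP. Of 18 interferon-stimulated genes 15 rose, 2 fell and 1 was not called, and of 14 MHC class I pathway genes 12 rose, 1 fell and 1 was not called, with the same counts adjusted over the list alone for both. Ifit3 rose by 6.36 ± 0.45 and Ifi47 by 2.53 ± 0.11 (camera, adjusted p = 3.62e-08, and adjusted p = 0.334 with an estimated correlation). Nlrc5 rose by 5.09 ± 0.26 and Psme1 by 1.55 ± 0.10 (camera, adjusted p = 7.8e-08, and adjusted p = 0.233 with an estimated correlation). Of 18 genes induced by T cell receptor signalling 16 rose, 1 fell and 1 was not called, with the same counts adjusted over the list alone. Myc rose by 2.63 ± 0.16 and Nab2 by 2.45 ± 0.18 (camera, adjusted p = 1.38e-07, and adjusted p = 0.309 with an estimated correlation). Of 14 dissociation and heat shock genes 3 rose and 2 fell, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.306). Of 29 cell cycle genes 1 rose, 19 fell and 9 were not called, and 2 rose and 19 fell when adjusted over the list alone. Kif11 fell by 1.90 ± 0.21 and Rrm2 fell by 1.58 ± 0.15, while Ccne1, which encodes cyclin E1, rose by 0.70 ± 0.12 (camera, adjusted p = 1.38e-04, and adjusted p = 0.521 with an estimated correlation). Of 8 Gimap family members 5 rose, 1 fell and 2 were not called, and 6 rose when adjusted over the list alone. Gimap4 rose by 6.71 ± 0.54 and Gimap3 by 5.66 ± 0.44, while Gimap9 fell by 0.67 ± 0.17 (camera, adjusted p = 0.00368, and adjusted p = 0.515 with an estimated correlation). Of 13 glycolysis genes 6 rose, 1 fell and 6 were not called, with the same counts adjusted over the list alone. Aldoa rose by 1.08 ± 0.08 and Pgam1 by 1.08 ± 0.11, while Pfkm fell by 0.69 ± 0.08 (camera, adjusted p = 0.0275, and adjusted p = 0.525 with an estimated correlation), a call lost without CD8SP replicate 2 (adjusted p = 0.0682). Of 11 chemokine and egress receptors 6 rose, 2 fell and 3 were not called, with the same counts adjusted over the list alone. S1pr1 rose by 4.63 ± 0.36 and Ccr8 by 3.80 ± 0.35, whereas Cxcr4 fell by 2.13 ± 0.50 and Ccr9 fell by 1.16 ± 0.12 (camera, adjusted p = 0.0405, and adjusted p = 0.548 with an estimated correlation). This call was lost without CD4SP replicate 1 or CD8SP replicate 1, with the replicate block and with the probe set of the smallest spread (adjusted p from 0.00965 to 0.0783 over the alternatives). Of 13 cholesterol biosynthesis genes 1 rose and 5 fell, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.0513), although it was called in 5 alternatives (adjusted p from 0.0354). Of 20 T cell receptor complex and signalling genes 8 rose, 7 fell and 5 were not called, with the same counts adjusted over the list alone (adjusted p = 0.602). Cd2 rose by 2.79 ± 0.15 and Themis fell by 2.02 ± 0.09, and without DP replicate 3 the number that fell was 4. Of 28 transcription factor genes 13 rose, 12 fell and 3 were not called, with the same counts adjusted over the list alone (adjusted p = 0.779). The median of this list was 0.27 and its mean 0.08, whereas camera ranked it towards lower values. Klf2 rose by 5.56 ± 0.31 and Runx3, which drives the CD8 lineage, by 1.96 ± 0.12, whereas Myb fell by 3.95 ± 0.10 and Satb1 fell by 1.41 ± 0.13.

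**Figure D3:**
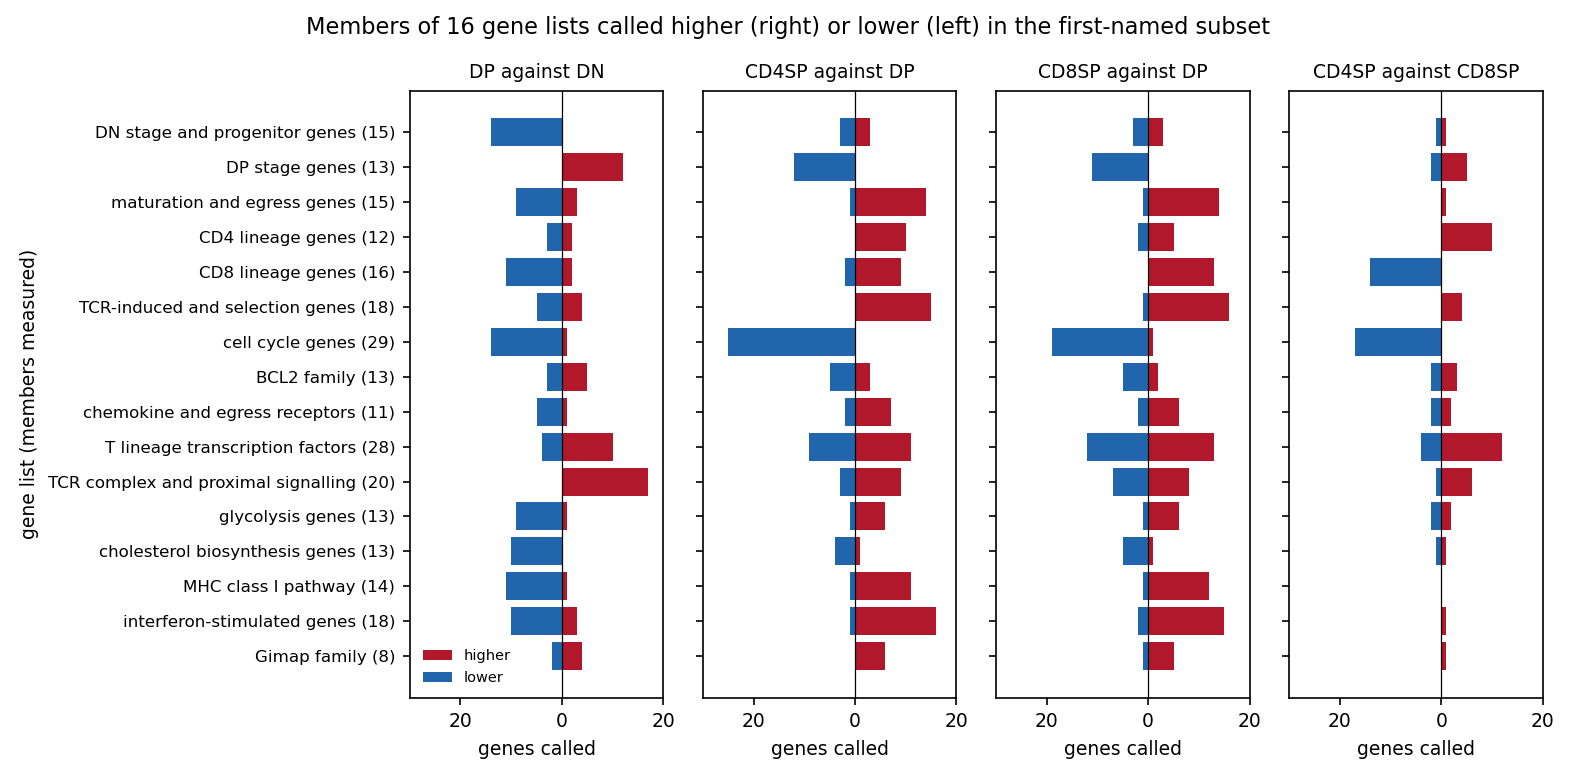
Number of members of each of 16 gene lists called higher (red, to the right) or lower (blue, to the left) in the first-named subset of each comparison, with the members measured in parentheses. Of 29 cell cycle genes, 14, 25, 19 and 17 were lower in DP against DN, CD4SP against DP, CD8SP against DP and CD4SP against CD8SP.

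Both single-positive subsets were compared with the same 3 DP arrays, and their differences from DP ran together. Across the 18193 genes, which are not independent replicates, the correlation of the log2 differences was 0.865. Simulated arrays without group differences, compared with 3 shared simulated DP arrays, gave 0.503 on average over 100 simulations. The covariance was 0.517, against 0.0235 simulated. In both subsets 2241 genes were higher than in DP and 2394 lower, where independent lists of these sizes would share 544 and 616. Another 66 genes were called in opposite directions, where independent lists would share 1161. The simulated counts of genes called in both were 0 on average for higher and 0.01 for lower. The DP arrays are 3 and could not be split into sets of at least 2 arrays. Simulated noise in shared DP arrays gave a covariance of at most 0.0258, which argues against noise as the source of most of the 0.517. Part of the overlap beyond independent lists may come from the shared controls, and a bias common to all 3 DP arrays was not tested. Genes higher than DP in CD4SP alone and also different between the single-positive subsets numbered 283, and those higher in CD8SP alone and different numbered 238.

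**Figure D4:**
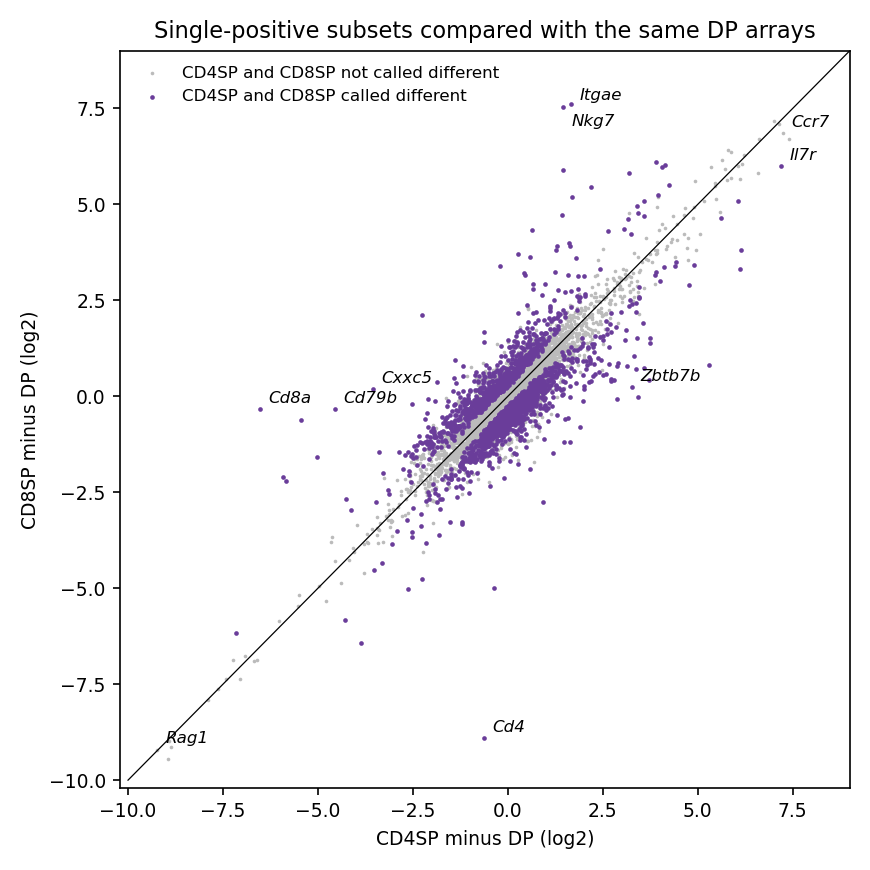
Log2 difference of each of 18193 genes in CD8SP (vertical) against that in CD4SP (horizontal), both relative to the same DP arrays, with the line of equality. Purple points are the 2308 genes called different between CD4SP and CD8SP. Cd4 lies at -0.64 and -8.90, and Itgae at 1.67 and 7.60.

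The fourth comparison set the 2 single-positive subsets against each other. In this comparison "rose" and "fell" mean higher and lower in CD4SP than in CD8SP, not a change from DP. The sort genes differed by 8.26 ± 0.50 (Cd4), -6.20 ± 0.38 (Cd8a) and -4.83 ± 0.29 (Cd8b1), each with an adjusted p of 5.68e-06. Besides these, the genes furthest higher in CD4SP were the choline dehydrogenase gene Chdh (4.61 ± 0.19) and the prostacyclin receptor gene Ptgir (4.49 ± 0.27). Relative to DP, the mean of Chdh was -0.38 in CD4SP and -4.98 in CD8SP, and that of Ptgir 5.31 and 0.82. Il17rb, a chain of the interleukin 25 receptor, was higher by 3.67 ± 0.24, Myo6 by 3.46 ± 0.34 and Tnfrsf4 by 3.30 ± 0.12. The value of Myo6 is the mean of 3 probe sets, each called higher, that ran from 0.90 to 5.16. Nkg7 and Itgae were lower in CD4SP, at -6.08 ± 0.39 and -5.93 ± 0.40, as were the NK receptor gene Klrd1 (-4.46 ± 0.42), Cd79b (-4.22 ± 0.44), Nt5dc2 (-3.80 ± 0.12) and Plac8 (-3.71 ± 0.23). Ighv14-2 was also lower (-4.39 ± 1.02, adjusted p = 0.0179), a call that was lost when CD4SP replicate 1 or 2 or CD8SP replicate 2 or 3 was left out, with adjusted p from 8.40e-04 to 0.07 over the alternatives. Chl1 was higher by 2.95 ± 0.11 as the mean of 4 probe sets that ran from 0.04 to 5.84, and was not called with the probe set of the smallest spread (adjusted p = 0.906, and from 7.94e-08 over the alternatives).

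In all, 1415 genes were higher and 893 lower in CD4SP than in CD8SP, of which 167 and 159 differed at least 2-fold, and for 30.3% of genes the 2 groups did not overlap (chance gives 10%). Single arrays weighed on these counts. Without CD4SP replicate 3, 811 genes were higher, and the number lower was 536 without CD4SP replicate 2, 563 without CD4SP replicate 3, 559 without CD8SP replicate 2, 538 without CD8SP replicate 3 and 1364 without CD8SP replicate 1. In the fit of only these 6 arrays, 828 were higher and 520 lower, and with the probe set of the highest mean 885 and 858.

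Of 12 CD4 lineage genes 10 rose, 0 fell and 2 were not called in CD4SP against CD8SP, and 11 rose when adjusted over the list alone. Zbtb7b was higher by 3.01 ± 0.21 and Gata3 by 1.80 ± 0.22, and the list also holds the sort gene Cd4. This was the only list call of the 4 comparisons that held with an estimated correlation (camera, adjusted p = 2.31e-12, and adjusted p = 0.041 with an estimated correlation), and 49 others were lost. Of 16 CD8 lineage genes 0 rose, 14 fell and 2 were not called, with the same counts adjusted over the list alone. The list holds the sort genes Cd8a and Cd8b1, and the chemokine gene Xcl1 fell by 3.43 ± 0.22 (camera, adjusted p = 5.77e-20, and adjusted p = 0.0842 with an estimated correlation). Of 28 transcription factor genes 12 rose, 4 fell and 12 were not called, and 13 rose and 6 fell when adjusted over the list alone. Ets1 rose by 0.94 ± 0.11, whereas Runx3 fell by 0.83 ± 0.12 and Eomes fell by 3.30 ± 0.63 (camera, adjusted p = 0.0048, and adjusted p = 0.496 with an estimated correlation). The call was lost with the probe set of the smallest spread (adjusted p = 0.239, and from 0.00287 over the alternatives), and the number that fell was 2 without CD4SP replicate 3 or CD8SP replicate 2. Zbtb16, which encodes PLZF, was higher by 1.96 ± 0.18, but its probe sets disagreed, and the one with the smallest spread gave -0.039.

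Cell cycle genes were lower in CD4SP than in CD8SP. Of 29 measured members 0 rose, 17 fell and 12 were not called, and 21 fell when adjusted over the list alone. Mcm6 fell by 1.12 ± 0.09, Cdc6 fell by 1.08 ± 0.13, Mcm3 fell by 0.85 ± 0.08 and Mcm7 fell by 0.71 ± 0.09 (camera, adjusted p = 4.01e-17, and adjusted p = 0.233 with an estimated correlation). Of 18 genes induced by T cell receptor signalling 4 rose, 0 fell and 14 were not called, and 9 rose and 2 fell when adjusted over the list alone. Itm2a was higher by 2.23 ± 0.10, Dusp5 by 1.43 ± 0.18, Nr4a1 by 1.38 ± 0.28 and Cd5, whose level follows the strength of receptor signalling, by 1.29 ± 0.22 (camera, adjusted p = 0.0048, and adjusted p = 0.521 with an estimated correlation). Without CD8SP replicate 1, and with the arrays numbered 1 as a factor, 2 members of this list fell. Of 20 T cell receptor complex and signalling genes 6 rose, 1 fell and 13 were not called, and 10 rose and 1 fell when adjusted over the list alone. Cd28 was higher by 1.63 ± 0.11 and Ptpn22 lower, at -0.74 ± 0.13 (camera, adjusted p = 0.00487, and adjusted p = 0.521 with an estimated correlation). Without CD4SP replicate 3, 2 of this list rose instead of 6.

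Of 13 DP stage genes 5 rose, 2 fell and 6 were not called in CD4SP against CD8SP, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.51). Those that fell were the sort genes Cd8a and Cd8b1. Besides Cd4, those that rose were Plxnd1 (2.39 ± 0.23), Satb1 (0.995 ± 0.13), Ets2 (0.73 ± 0.17) and Cd1d1 (0.62 ± 0.12). Of 13 BCL2 family members 3 rose, 2 fell and 8 were not called, and 4 rose and 4 fell when adjusted over the list alone (adjusted p = 0.54). Bcl2l1 rose by 0.88 ± 0.15, whereas Bid fell by 0.96 ± 0.17, and without CD4SP replicate 1 the number that rose was 1. Of 15 DN stage genes 1 rose and 1 fell, as did 1 and 1 of 13 cholesterol biosynthesis genes, with the same counts adjusted over the list alone for both (adjusted p = 0.675 and 0.454). Of 8 Gimap family members 1 rose, and 3 rose and 1 fell when adjusted over the list alone (adjusted p = 0.306). The number that rose was 3 without DN replicate 1 or 3 and with the arrays numbered 1 as a factor.

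Of 15 maturation and egress genes Il7r alone was called (1.21 ± 0.36, adjusted p = 0.0499), a call lost in 12 of its 21 alternatives (adjusted p from 0.00103 to 0.241), and 0 were called when adjusted over the list alone. The standard error of Il7r pools all 4 groups, with SDs of 0.07 in CD4SP, 0.04 in CD8SP, 0.74 in DN and 0.65 in DP. Of 18 interferon-stimulated genes 1 rose, Stat2 (0.67 ± 0.09), with the same count adjusted over the list alone, and 2 fell without CD8SP replicate 1 or DN replicate 1 and 3 with the arrays numbered 1 as a factor. Of 14 MHC class I pathway genes 0 were called, also when adjusted over the list alone, and their median difference was -0.07. Without CD8SP replicate 1, 4 of them fell, and with the arrays numbered 1 as a factor 2. Of 11 chemokine and egress receptors 2 rose, Ccr8 (2.33 ± 0.35) and Ccr4 (1.71 ± 0.31), and 2 fell, among them Cxcr6 (-3.27 ± 0.56), while 3 rose and 3 fell when adjusted over the list alone (adjusted p = 0.727, median 0.03, mean -0.01). With the arrays numbered 1 as a factor 4 fell. Of 13 glycolysis genes 2 rose and 2 fell, with 3 and 2 adjusted over the list alone (adjusted p = 0.748), and 4 rose without CD8SP replicate 2.

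Among the marker lists, 5 of 7 regulatory T cell markers rose in CD4SP against CD8SP and 1 fell, with the same counts adjusted over the list alone. They included Ctla4 (1.35 ± 0.21), Tnfrsf18 (1.12 ± 0.22) and Gpr83 (1.01 ± 0.17), and Ctla4, Tnfrsf4 and Foxp3 are also in the CD4 lineage list (camera, adjusted p = 5.94e-04, and adjusted p = 0.0976 with an estimated correlation). Foxp3 itself was not called here, and rose in CD4SP against DP by 0.49 ± 0.16. Of 9 NK cell and innate lymphoid markers 3 fell, among them Klrd1 and Eomes, which are also in the CD8 lineage list (camera, adjusted p = 0.0337, and adjusted p = 0.53 with an estimated correlation), a call lost without CD8SP replicate 1 and with the probe set of the smallest spread (adjusted p from 0.0193 to 0.0723 over the alternatives). Of 9 B cell markers 2 fell, and Cd79b alone fell by over 2-fold. Of 15 myeloid markers 1 fell, Cst3 (-0.40 ± 0.08), and 2 rose without DN replicate 1. Of 5 γδ T cell markers 2 rose, Zbtb16 and Maf (0.66 ± 0.17, a call lost when any CD4SP array or CD8SP replicate 1 or 2 was left out), with the same count adjusted over the list alone (camera, adjusted p = 0.0184, and adjusted p = 0.48 with an estimated correlation), and the list call was lost with the probe set of the smallest spread (adjusted p = 0.954, and from 0.00319 over the alternatives), where Maf turned to -0.22. With the probe sets of below-median spread Maf turned to -0.13. Of 5 erythroid and 12 thymic stroma markers 0 were called. Of 14 dissociation and heat shock genes 2 rose, Dusp1 (1.38 ± 0.11) and Zfp36 (0.52 ± 0.14), the latter lost in 6 alternatives. Among 4 sex-linked genes the Y-linked Uty (0.58 ± 0.08) and Kdm5d (0.41 ± 0.11) were higher in CD4SP. The Kdm5d call was lost in 12 alternatives, and Uty was also lower in CD8SP than in DP (-0.75 ± 0.08).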

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

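The difference between the changes of the 2 single-positive subsets from DP was tested by the planned CD4SP against CD8SP comparison (limma), and no test in this part was chosen after the results were seen. Of the 28 genes named by size or as sort genes in the comparisons with DP, 8 differed between the subsets, against 12.7% of all genes. The 28 were picked from the same arrays by the size of their change in either subset. That can favour genes that differ between the subsets, so the count of 8 is not a result about them. Cd4 was higher in CD4SP by 8.26, and Cd8a and Cd8b1 differed by -6.20 and -4.83, as the gates select. Itgae rose from DP by 1.67 in CD4SP and 7.60 in CD8SP, a difference of -5.93 (adjusted p = 1.09e-05). Nkg7 rose by 1.45 in CD4SP and 7.52 in CD8SP, a difference of -6.08 (adjusted p = 7.37e-06). Ccr8 rose by 6.13 in CD4SP and 3.80 in CD8SP, a difference of 2.33 (adjusted p = 0.00175). Ly6d fell by 7.16 in CD4SP and 6.17 in CD8SP, a difference of -0.99 (adjusted p = 0.0239). Il7r rose by 7.20 in CD4SP and 5.99 in CD8SP, a difference of 1.21 (adjusted p = 0.0499), which lost its call in 12 of 21 alternatives. The fit pools the spread of all groups, and Il7r had SDs of 0.07 in CD4SP and 0.04 in CD8SP, against 0.74 in DN and 0.65 in DP. The gap test for a single outlying value was not applied, since each group holds 3 arrays.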

How the results depend on the processing

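The variance trend and the probe set of the highest mean were the preset design and became alternatives after the values were seen. The probe set of the smallest spread, the restriction to probe sets of below-median spread, the arrays numbered 1 as a factor and the joint omission of DN replicate 1 and CD8SP replicate 1 were chosen after seeing the data. For named genes, 9676 of 10051 values under 22 alternatives kept direction and call, 351 lost the call, 5 gained one and 19 changed sign. For lists, 1704 of 1800 kept both, 87 lost the call (49 of them with the estimated correlation) and 9 gained one. The cause of the changes below was not tested unless stated. Testing all 34945 probe sets raises counts by construction: 6595 higher and 6233 lower in DP against DN, 5123 and 5856 in CD4SP against DP, 5733 and 7983 in CD8SP against DP, and 2921 and 1572 in CD4SP against CD8SP, with a correlation of 0.857 between the changes from DP. The probe set of the highest mean is the one most above DP. It gave 2253 higher and 3862 lower in DP against DN, 3388 and 2054 in CD4SP against DP, 4003 and 2483 in CD8SP against DP, and 885 and 858 in CD4SP against CD8SP, with a correlation of 0.856. For CD4SP against CD8SP, only the 6 arrays compared, with fewer residual degrees of freedom, gave 828 higher and 520 lower. Array weights gave 1589 lower (correlation 0.858), the probe sets of below-median spread 1372 lower (correlation 0.881), and the joint omission of both arrays 1441 lower (correlation 0.853). Leaving out 1 array at a time gave 2541 to 3540 higher and 2923 to 3678 lower in DP against DN, 2362 to 3322 and 2434 to 3246 in CD4SP against DP, 2779 to 3406 and 3196 to 3796 in CD8SP against DP, and 811 to 1515 and 536 to 1364 in CD4SP against CD8SP, with correlations from 0.853 to 0.869. Where this left 2 arrays in a group, the spread came from all groups.

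Signs changed where the probe sets of a gene disagreed. With the probe set of the smallest spread and with the probe sets of below-median spread, Tnfrsf9 turned to 0.61 in DP against DN, -0.30 in CD4SP against DP and -0.24 in CD8SP against DP, Cd163l1 to -2.0e-04 in CD8SP against DP and Epcam to 0.23 in DP against DN. With either of these or the probe set of the highest mean, Bmf turned to 0.018 in CD8SP against DP. With the probe set of the smallest spread, Zbtb16 turned to -0.039 and Maf to -0.22 in CD4SP against CD8SP (Maf to -0.13 with below-median spread), and Krt14 to -0.018 and Ighm to 0.23 in CD4SP against DP (Ighm to 0.15 with the highest mean). The replicate numbers were not taken to pair the arrays in the main fit, as the preset design had it, with the replicate block as an alternative. Residuals of arrays from different groups correlated by 0.11 to 0.16 for number 1, -0.03 to 0.09 for number 2 and 0.02 to 0.14 for number 3. For different numbers they correlated by -0.16 to 0.08. A shared batch of arrays with the same number is therefore not excluded. Every array but CD4SP replicate 2 correlated best with one of its own number, a hint from the data and not from the design. With the replicate block, 3507 genes were higher and 3593 lower in DP against DN, 3162 and 3130 in CD4SP against DP, 3438 and 3990 in CD8SP against DP, and 1723 and 1081 in CD4SP against CD8SP. The block raised the number of cell cycle genes that rose in DP against DN from 1 to 6 and of dissociation genes that rose in CD8SP against DP from 3 to 5. In CD4SP against CD8SP it raised the numbers that fell from 0 to 3 for interferon-stimulated, 2 for MHC class I and 2 for receptor-induced genes, of which 7 rose instead of 4. It ended the list calls of γδ T cell markers in CD4SP against DP (adjusted p = 0.0597, and 0.0231 to 0.532 over the alternatives) and of chemokine receptors in CD8SP against DP (adjusted p = 0.0509, and 0.00965 to 0.0783). Over all lists, counts of called members moved by over 1.5 times and at least 2 genes in 69 cases with the probe sets of below-median spread, which hold fewer genes, in 15 with array weights and in at most 12 under each other alternative. Centring changed the share of higher calls from 61.3% to 53.5% in CD4SP against CD8SP and by less elsewhere. Pseudocounts, the floor, quantile normalization and filters on dim probe sets were not run, since the values are log differences from DP, which hold no signal over background.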

Other observations

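Apart from the counts over other splits of the arrays, the tests in this part were chosen after the results were seen, and so were the genes named in its first 2 paragraphs. DP cells held the lowest or the highest level of many genes. Of 18193 genes, 1138 were called lower in DP than in each of the other subsets and 1165 higher. Independent lists would share 102 and 110, and simulated unchanged groups gave 0 on average, although these comparisons share the DP arrays. The values for independent lists are too low a reference, since the CD4SP and CD8SP lists shared 2241 genes higher than DP and 2394 lower. Il7r lay above DP by 4.92 in DN, 7.20 in CD4SP and 5.99 in CD8SP. Smad7 lay above it by 4.52, 7.01 and 7.17, the cyclin gene Ccnd2 by 4.45, 6.62 and 6.70, and Sema4a by 4.25, 5.63 and 6.16. The genes highest in DP included Slc7a11 (DN at -6.91, CD4SP at -6.69 and CD8SP at -6.89), Chrna9 (-4.76, -6.03 and -5.85), the relaxin family gene Insl5 (-3.26, -3.79 and -3.86) and the metalloprotease gene Adam12 (-3.39, -3.13 and -3.06).

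Cd79b, which encodes a signalling chain of the B cell receptor, was low in CD4SP alone. It lay at -5.07, -4.09 and -4.47 on the CD4SP arrays, between -0.79 and -0.08 on the CD8SP arrays and between -0.37 and 1.47 on the DN arrays, from 1 probe set. Ms4a1 lay between 0.38 and 0.43 on the CD4SP arrays, and Ighm was the other B cell marker called lower in CD4SP than in CD8SP (-0.39), a call lost in 6 of 22 alternatives (adjusted p up to 0.876), CD4SP replicate 1 or 3 or CD8SP replicate 2 left out among them. Gzma, a granzyme gene, was lower in CD4SP than in DP by -4.13 ± 0.34 and in CD8SP by -2.96 ± 0.34, whereas Klrd1 rose by 5.90 ± 0.42 in CD8SP.

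Cd4, Cd8a and Cd8b1 were higher on DN replicate 1 than on the other DN arrays (Cd4 at -3.88 against -6.49 and -5.29). Ms4a1, Lyz2 and Tyrobp were lower there (by -2.45, -1.95 and -1.60), as with fewer non-T cells. Lyl1, a member of the DN stage list, was also lower (by -3.89). Fewer non-T cells would, however, raise genes that only T lineage cells express as much as Cd4, which lay 2.01 higher. The median rise of 20 T cell receptor complex and signalling genes, not all confined to T cells, was -0.14 (SD 0.21). Cd3e, of the receptor complex itself, differed by -0.09. For Cd4, DP cells would need a share of 5.11%, which would put every transcript of DP cells at -4.29 or above. Slc7a11 (-6.80) and A930003A15Rik (-7.17) lay more than 1 below this. Their values on the other DN arrays were similar (-7.08 and -6.84 for Slc7a11, -7.18 and -7.06 for A930003A15Rik). These 2 genes go against such a share, but 3 had been set as the bound, so the test did not decide. Cd8b1 and Cd8a need 9.42% and 10.9%, and 4 genes lay more than 1 below the -3.41 of Cd8b1. That argues against DP cells for Cd8a and Cd8b1, narrowly, since Slc6a19 and Medag lay at -1.11 and -1.03 from the -3.41. CD4SP cells cannot have raised Cd8a and Cd8b1, by 1.64 and 1.26, since their means of these genes, relative to the lower of the other DN arrays, were -1.94 and -1.45 (SD up to 0.26). For Cd4 alone CD4SP cells would need a share of 7.97%. That share would put each of 10 genes raised in CD4SP at or above a needed level. Their median lay at -0.64 (SD 1.70) from that level, above the bound of -1, and 3 of the 10 lay above the level. Ccr7 (-4.74), Gimap4 (-2.41), Ifi27l2a (-2.01) and Ifit1 (-1.63) lay more than 1 below it and go against such a share. By its bound the test of CD4SP cells did not decide. Other admixtures and a difference between animals were not tested.

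Zbtb16 and Il17rb were higher in CD4SP than in CD8SP by 1.96 and 3.67, although 1 probe set of Zbtb16 gave -0.039. Relative to DP, the mean of Zbtb16 was 2.50 in CD4SP and 0.54 in CD8SP. That of Il17rb was 0.92 in CD4SP and -2.75 in CD8SP, so much of its difference lay below DP in CD8SP. Invariant NKT cells, which carry TCRβ and may enter the CD4SP gate, are a candidate source, but 1 of 13 other measured NKT genes was called higher (Il4, by 0.58), where 0.5 of them had been asked for, and the median difference was 0.06 (SD 0.50), with Tbx21 (-0.86) and Il18r1 (1.31, adjusted p = 0.106) the lowest and highest. Trav11 and Trav11d are not analysed here, and 3 of the 13 genes had been seen before the list was written. For γδ T cells, which the TCRβ gate would remove, the median of 4 other markers was 0.39 (SD 0.30, 1 called). Neither source is decided by these values, and a difference of the CD4 lineage itself was not tested apart from them.

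Cell cycle genes were lower in CD4SP than in CD8SP. DP cells in the CD8SP gate would need a share of 28.9%, but the highest CD8SP value among Rag1, Rag2 and Arpp21 was -6.88 (SD 0.47), far below the needed -1.79. CD8SP replicate 1, which stood apart, does not carry the difference alone: without it the median of the list was -0.65, against -0.73 with it, and 16 genes were lower instead of 17. These values argue against both sources. A difference between the subsets themselves, such as more cycling cells in CD8SP, stays open and was not tested, nor were other admixtures.

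The arrays of each pair of groups can be split in 10 ways, too few for a share under 0.05. The real split was the 1 with as many called genes in each comparison. Each other split mixes arrays of both groups, so that the group difference enters the spread and few calls follow by construction. No conclusion is drawn from these counts. DP against DN gave 6660, and the other splits at most 0. CD4SP against DP gave 5942, CD8SP against DP 7103 and CD4SP against CD8SP 2308, where the other splits gave at most 0, 0 and 1.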
